A study of Mus musculus with 6 samples.

How the data were processed

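Gene expression was measured in 6 mouse samples, 3 of embryonic stem cells (ESC, line R1/E) and 3 of spermatogonial stem cells (SSC, strain C57BL/6), on 1-colour Illumina bead arrays of 45281 probes. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns with a DNase step and turned into biotin-labelled cRNA. The labels number the replicates of each group 1 to 3 and do not state that they were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. No culture condition, sort or isolation step of the cells is given in the sources used here.

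The deposited table of intensity values holds 1 mean probe brightness per probe and array on a linear scale, without normalization between arrays and with the background still in it. The same deposited table gives a detection p-value per probe and array. GenomeStudio is named, without a version, per the submitters' processing notes. A further deposited table by the authors holds processed intensity values. Its columns share the same quantiles on a linear scale, their medians lie between 107.09 and 107.14, and each ranks the probes as the unnormalized column of the same sample does, with a rank correlation of at least 0.9998872. How the authors made that table is not given in the sources used here, and it served as an alternative starting point. No array held values identical to another array's, and 0 value columns were left without a sample.

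Background was corrected by normexp with parameters inferred from the detection p-values and an offset of 16, and arrays were then quantile normalized and log2 transformed (limma 3.58.1 in R 4.3.3). A probe was kept when its detection p was under 0.01 on at least 3 of the 6 arrays, which left 17435 probes. Each kept probe was fitted with lmFit and eBayes, without covariates, and p-values were adjusted by Benjamini and Hochberg over all kept probes. A gene was called at an adjusted p under 0.05. Differences are SSC minus ESC, so a positive value is higher in SSC.

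Probes were named through the platform's annotation. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 are unnamed here. Of the named probes, 34807 matched the RefSeq table of assembly GRCm38.p6 by gene identifier, and 0 symbols changed. Each of the 10024 genes measured, of 19057 with a probe, was represented by its kept probe with the highest mean over the 6 arrays. Of the 3561 genes with more than 1 kept probe, 211 had kept probes called in opposite directions. Coordinates were not used here.

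A probe whose detection p was 0.01 or more on every array of a group has only a bound there. For such a probe the text gives "at least N-fold", from the bright group's mean log2 value against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes. No fold is given where this came to less than 1. Such a bound holds only under the background correction and normalization described above, and other settings can give smaller folds. For named genes detected on 1 or 2 of the 3 arrays of a group the same bound is given, a choice made after seeing the data. Every fold and difference is that of the gene's brightest probe unless another is named. Adjusted p-values of such genes come from the fitted values.

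Before the data were examined, 22 gene lists were fixed: core and naive pluripotency, undifferentiated spermatogonia, differentiating spermatogonia, germ granule and piRNA pathway, meiotic prophase, spermatid, Rhox homeobox cluster, Sertoli cell, Leydig cell, fibroblast and peritubular myoid cell, macrophage and leukocyte, endothelial cell, early embryonic lineages, DNA methylation, Polycomb and H3K9 methylation, paternally and maternally expressed imprinted genes, proliferation, glycolysis, mitochondrial oxidative phosphorylation, FGF, GDNF and LIF signalling, and Y-linked and X-inactivation. Each list was compared with all other genes by camera at a preset inter-gene correlation of 0.01, with adjustment over the 22 lists. Camera with an estimated correlation and fry were alternatives. The genes named in the text were chosen by a rule set at the same time. It takes the 5 largest called differences per direction among genes detected on all 6 arrays without overlap between the groups, and the 5 largest bounds per direction. It adds per list up to 4 called members of the largest size and up to 2 going against the list's majority, and 14 stem cell and germ cell genes called or not. Symbols of clones and unnamed predictions were passed over.

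Alternatives fixed at that time were no background correction, scaling on array medians, cyclic loess, the authors' processed table, no detection filter, detection on all 6 arrays, a detection limit of 0.05, the mean of all kept probes of a gene, a trended and robust prior, an adjusted p under 0.01, the replicate number as a block, and each sample left out in turn. The fit was tested on simulated data with the means and spreads of the 17435 kept probes and 200 changed probes. It recovered 97.0% of the probes changed by 2 on the log2 scale, 83.6% of those changed by 1 and 21.2% of those changed by 0.5, and 2.88% of its calls were false. In the data 74.4% of genes were called, so the adjusted threshold was stricter in the simulation and these shares do not carry over. Changes were added after normalization, which the simulation did not test. Of 20 simulated lists of 20 genes, camera called the 1 list shifted by 0.5 and 0 of the others. Simulated probes were drawn independently, so these lists do not test the preset correlation. In the data the estimated correlation was, for instance, 0.228 for the proliferation list. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.130.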

Results

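The series profiled mouse spermatogonial stem cells, the self-renewing germ cells of the testis, and embryonic stem cells, pluripotent cells from the early embryo, to compare their gene expression. Each group had 3 samples on 1 array each. Probes detected numbered 15613, 15242 and 15363 on the ESC arrays and 17211, 16997 and 16505 on the SSC arrays. Over the kept probes, arrays of the same group correlated at 0.989 to 0.993 and arrays of different groups at 0.784 to 0.795. The first principal component held 94.5% of the variance and separated the groups. The median SD within a group was 0.156 on the log2 scale, and the median absolute difference between groups was 0.65.

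SSC and ESC differed in most of the genes measured. Of 10024 genes, 7460 (74.4%) were called, 3798 higher and 3662 lower in SSC, and 2564 were not called. A difference of at least 2-fold was called for 3331 genes (33.2%), 1751 higher and 1580 lower. There were 850 called genes detected on all SSC arrays and no ESC array, and 400 with the reverse pattern. The 3 values of SSC and the 3 of ESC did not overlap for 76.9% of genes, against 10% by chance. The 2-fold count depended on the background correction: it was 1409 without one and 1550 from the authors' processed table. It was 2159 where detection on all 6 arrays was required, and under scaling on array medians 63.6% of the 2-fold calls were higher in SSC, against 52.6% here.

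Among genes detected on all arrays, the largest differences toward SSC were Akr1cl, with a log2 fold change of 6.66 ± 0.11 (SE, n = 3 per group), Phf20l1 (6.43 ± 0.12), Tbccd1 (6.40 ± 0.13), Dlk1 (6.09 ± 0.13) and Ifi27 (5.85 ± 0.14). The other kept probe differed by 1.61 for Akr1cl, 0.50 for Phf20l1 and 4.96 for Dlk1, and the mean of kept probes was 4.13 for Akr1cl and 3.46 for Phf20l1. The largest differences toward ESC were Ooep, a maternal-effect gene of the oocyte and early embryo, at −7.22 ± 0.15, Gtsf1l (−6.25 ± 0.12), Epop, a Polycomb-associated factor (−6.18 ± 0.15), the amino acid transporter Slc7a3 (−5.48 ± 0.11) and Lgals3 (−5.43 ± 0.13). The other kept probe of Gtsf1l was at −3.94. Among genes with no probe detected in ESC, Defb19, a beta-defensin, was at least 281-fold higher in SSC. Tmem114 followed at least 270-fold higher, Tmem255a at least 202-fold, Strip2 at least 145-fold and Dcn, the matrix proteoglycan decorin, at least 93.8-fold. The other kept probe differed by 0.99 for Strip2, 3.23 for Tmem255a and 4.36 for Dcn, and the mean of kept probes was 4.24 for Strip2. In the other direction Bcat1 was at least 73.5-fold lower in SSC and not detected there, Nanog at least 53.9-fold, Kdelr3 at least 48.8-fold, Esrrb at least 43.4-fold and Nodal at least 30.8-fold. The other kept probe was at −4.51 for Nanog and −2.66 for Nodal. The adjusted p of these 20 genes in limma was 2.81e-11 or less. Of the 122 genes named here and measured, 65 had log2 differences more than 1.5 times smaller without background correction, and 55 from the authors' processed table. Of the 22 list medians, 16 and 15 were smaller by that much in these settings. The folds given as bounds hold only under the main background correction and normalization. On the log2 scale the bound of Dcn was 6.55 and that of Nanog −5.75. Without background correction their fitted differences were 4.66 and −3.77, smaller in size than those bounds.

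Pluripotency genes were lower in SSC almost without exception. Of 30 measured members of the core and naive pluripotency list, 29 were lower, 28 of them at least 2-fold, 0 were higher and 1 was not called. Nanog and Esrrb, transcription factors of the naive state, were detected on every ESC array and on 0 SSC arrays. Sox2 fell by 3.78 ± 0.12 on the log2 scale, from 10.05 to 6.27, and its other kept probe was at −2.07. Klf4 fell by 3.14 ± 0.17, from 9.72 to 6.58. Its value was −1.91 with the mean of its 3 kept probes and −1.15 without ESC replicate 1, where another probe was the brightest. Nr0b1, detected on 2 of 3 SSC arrays, was at least 43.9-fold lower. Pou5f1, which encodes Oct4, kept a high level in SSC: it was 10.62 ± 0.13 (SD, n = 3) in ESC and 9.41 ± 0.12 (SD, n = 3) in SSC, a difference of −1.21 (adjusted p = 1.55e-06). Lin28a, an RNA-binding protein of stem and germ cells, was lower by a difference of −0.80 (adjusted p = 3.03e-05), or −1.39 with the mean of its kept probes. No probe of Myc passed the detection filter. The list's median was −3.58 (camera adjusted p = 4.28e-15), and it was the 1 list called with an estimated correlation (adjusted p = 0.0234).

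**Figure D1:**
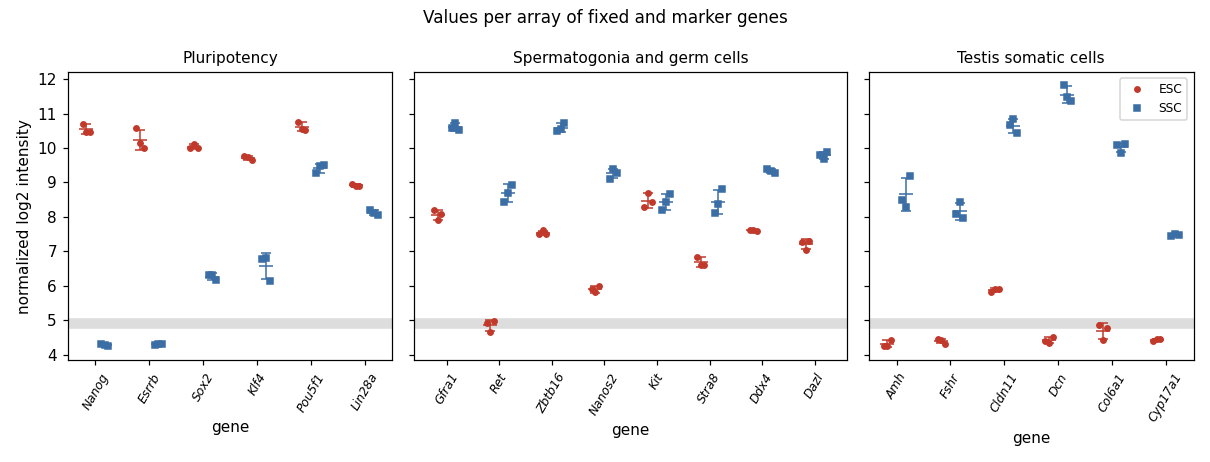
Normalized log2 intensity (y axis) of 20 genes (x axis) on the 3 ESC arrays (circles) and 3 SSC arrays (squares), with the mean and SD of each group as bars, and a grey band spanning the arrays' lowest values among detected probes. Nanog and Esrrb lie under the band on the SSC arrays, Pou5f1 stays at 9.41 in SSC, Kit overlaps between the groups, and Amh, Fshr, Dcn and Cyp17a1 lie under the band on the ESC arrays.

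Genes of spermatogonia were mostly higher in SSC. In the list for undifferentiated spermatogonia, 20 of 28 measured members were higher, 5 lower and 3 not called, with a median of 1.10, or 1.04 with genes undetected in a group at their bound. Gfra1 and Ret encode the receptors for GDNF, the niche factor of spermatogonial stem cells. Gfra1 was higher by 2.55 ± 0.13 (SE) and Ret by at least 12.9-fold, with 0 ESC arrays detecting it, while the other kept probe of Ret differed by 2.40. Zbtb16 (3.05 ± 0.12), Nanos2 (3.36 ± 0.12), Taf4b (3.63 ± 0.14) and Neurog3 (at least 11.6-fold, detected on 1 of 3 ESC arrays), all known in early spermatogonia, were higher too. Upp1 (−4.93 ± 0.14) and the surface antigen Cd9 (−1.99 ± 0.15) went the other way. Camera called this list (adjusted p = 0.00255), and its adjusted p was 0.188 with an estimated correlation. Its median was 0.473 without background correction and 0.518 from the authors' processed table.

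Of the 10 genes for differentiating spermatogonia, 9 were higher, 0 lower and 1 not called, with a median of 2.30, or 1.88 with bounds. Sohlh1, a transcription factor of spermatogonial differentiation, was at least 75.2-fold higher and detected on 2 of 3 ESC arrays. Ccnd2 was higher by 3.90 ± 0.13, with another kept probe at 2.29, and Stra8, the retinoic acid response gene of meiotic entry, by 1.75 ± 0.16. Tex101 was at least 11.6-fold higher. Kit, the receptor that marks differentiating spermatogonia, was 8.48 ± 0.21 (SD, n = 3) in ESC and 8.43 ± 0.23 (SD, n = 3) in SSC and was not called (adjusted p = 0.812). It was called with the mean of its kept probes (−0.32), and its difference turned to 0.12 under scaling on array medians, to 0.072 without ESC replicate 2 and to 0.077 without SSC replicate 1. The list's camera adjusted p was 2.25e-04, and its adjusted p was 0.188 with an estimated correlation. Its median was 1.10 without background correction, 1.19 from the authors' processed table and 1.51 with detection on all 6 arrays.

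Components of the germ granule and of the piRNA pathway, which silences transposons in germ cells, were higher for 18 of 20 measured members. A single member was lower (Rnf17, −1.13 ± 0.14) and 1 was not called. Asz1, detected on 1 of 3 ESC arrays, was at least 12.02-fold higher. Piwil2 was higher by 3.20 ± 0.12, Tdrd7 by 3.17 ± 0.14 and Tdrd9 by at least 8.70-fold. Ddx4, the germ cell RNA helicase, was higher by 1.72 ± 0.11 and Dazl by 2.58 ± 0.12, and both were detected on all 3 ESC arrays, at 7.61 and 7.21, while the other kept probe of Dazl differed by 1.28. The median was 1.48 (camera adjusted p = 2.65e-05, and adjusted p = 0.120 with an estimated correlation), or 0.976 without background correction.

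Of 22 meiotic genes with a probe, 16 were measured, and Sycp3, Dmc1, Mei4 and Hormad1 were among those that did not pass the detection filter. Of the 16, 13 were higher, 1 was lower (Mlh3, −0.99 ± 0.12) and 2 were not called. Detection on all 6 arrays would leave 10 of the 16 and remove 6, all higher in SSC. Spo11, which makes the meiotic DNA breaks, was at least 7.17-fold higher by its brightest probe, with the other at a difference of 1.35. The synaptonemal complex gene Sycp2 was at least 5.21-fold higher, Tex11 higher by 2.94 ± 0.13 and Syce3 by 2.28 ± 0.15. The median was 1.35, or 1.17 with bounds (camera adjusted p = 5.61e-04, and adjusted p = 0.190 with an estimated correlation), or 0.637 without background correction and 0.696 from the authors' processed table. Of 19 spermatid genes with a probe, 3 were measured, 2 were higher (Ldhc, 1.23 ± 0.30, and Catsper2, 0.75 ± 0.12) and 1 was not called (adjusted p = 0.364). Ldhc fell to 0.75 without SSC replicate 3, which stood at 9.47 against 8.08 and 7.95 on the other SSC arrays. In the X-linked Rhox homeobox cluster, 3 of 6 measured genes were lower (Rhox5, −2.18 ± 0.14, and, detected on 1 of 3 SSC arrays each, Rhox9, at least 8.63-fold, and Rhox6, at least 2.66-fold), 2 were higher (Rhox13, 1.13 ± 0.12, and Rhox10, 0.72 ± 0.15) and 1 was not called, and the list was not called (adjusted p = 0.476).

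Most measured markers of Sertoli cells and of fibroblast and peritubular myoid cells were higher in the same SSC samples as these germ cell genes. Of 9 measured Sertoli cell genes, the nurse cells of the seminiferous tubule, 6 were higher, 2 lower and 1 not called. Cldn11, a tight junction protein of Sertoli cells, was higher by 4.77 ± 0.13, the hormone gene Amh by at least 12.6-fold, the FSH receptor Fshr by at least 8.92-fold and the inhibin gene Inha, detected on 1 of 3 ESC arrays, by at least 9.49-fold. Rhox5 and Dhh (−0.37 ± 0.13, adjusted p = 0.0184) were lower, and the call of Dhh was lost without ESC replicate 3 (−0.32) and without SSC replicate 1 (−0.28). It was also lost without background correction (−0.10), under scaling on array medians (−0.090) and from the authors' processed table (−0.12). The median was 3.52, or 2.92 with bounds, and the camera adjusted p was 0.0259. That median was 1.52 without background correction, 1.66 from the authors' processed table, 2.28 without a filter or at a detection limit of 0.05, and −0.068 with detection on all 6 arrays, a filter that removes 5 of the 9 members, all higher in SSC and undetected on 2 or 3 ESC arrays. The call was lost with an estimated correlation (adjusted p = 0.188) and, over the 4 members left by that filter, at an adjusted p of 0.872.

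Fibroblast and peritubular myoid genes were higher for 13 of 16 measured members, lower for 2 and not called for 1. Dcn, Col6a1 (at least 32.5-fold), Col1a1 (at least 9.18-fold, detected on 2 of 3 ESC arrays) and the receptor Pdgfra (3.51 ± 0.13) were higher. Fibronectin, Fn1, was lower (−1.98 ± 0.12, with the smallest of its 4 kept probes at −0.83), as was Tagln, at least 1.31-fold and undetected on the SSC arrays. The median was 1.89, or 1.40 with bounds (camera adjusted p = 3.92e-04, and adjusted p = 0.194 with an estimated correlation), or 0.771 without background correction and 0.822 from the authors' processed table. The call was also lost where detection on all 6 arrays was required (adjusted p = 0.128), which leaves 6 of the 16 members and removes 9 that were higher. Leydig cells serve steroid synthesis. Of 9 of their listed genes with a probe, 4 were measured, 3 of them higher and 1 lower. Star, Hsd3b1, Hsd3b6, Nr5a1 and Fdx1 did not pass the detection filter. Cyp17a1 was at least 5.52-fold higher, Hsd17b3 at least 3.97-fold higher and Insl3 higher by 0.80 ± 0.16, while Cyp11a1, detected on 2 of 3 SSC arrays, was at least 2.18-fold lower, and the list was not called (adjusted p = 0.228). Insl3 was higher by 1.26 with the mean of its kept probes.

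Other cell types gave mixed counts. The macrophage and leukocyte list had 12 members with a probe, of which 5 were measured, 3 higher, 1 lower and 1 not called. Fcer1g was at least 1.37-fold higher and Lyz2 at least 1.14-fold, C1qc was detected on the SSC arrays alone, and Laptm5 was lower (−3.72 ± 0.12). The list's median (0.67) and mean (−0.18) differ in sign, and it was not called (adjusted p = 0.552). Endothelial genes split evenly, with 3 of 8 higher and 3 lower, including Cdh5 (at least 1.99-fold higher), Vwf (−1.75 ± 0.12), Egfl7 (−1.59 ± 0.12, other kept probe −0.91) and Eng (−1.04 ± 0.13), and the list was not called (adjusted p = 0.828). Of 18 genes of early embryonic lineages with a probe, 7 were measured, 4 of them lower, 2 higher and 1 not called. Otx2, a factor of the primed epiblast, was at least 11.03-fold lower, the keratin Krt8 was lower by a difference of −2.79 ± 0.16, Krt18, detected on 1 of 3 SSC arrays, at least 6.19-fold lower, and Gata6 was higher (2.11 ± 0.16), as was Gata4, at least 1.20-fold (list adjusted p = 0.208). Gata4 is also on the Sertoli cell list and was counted there among the higher genes.

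**Figure D2:**
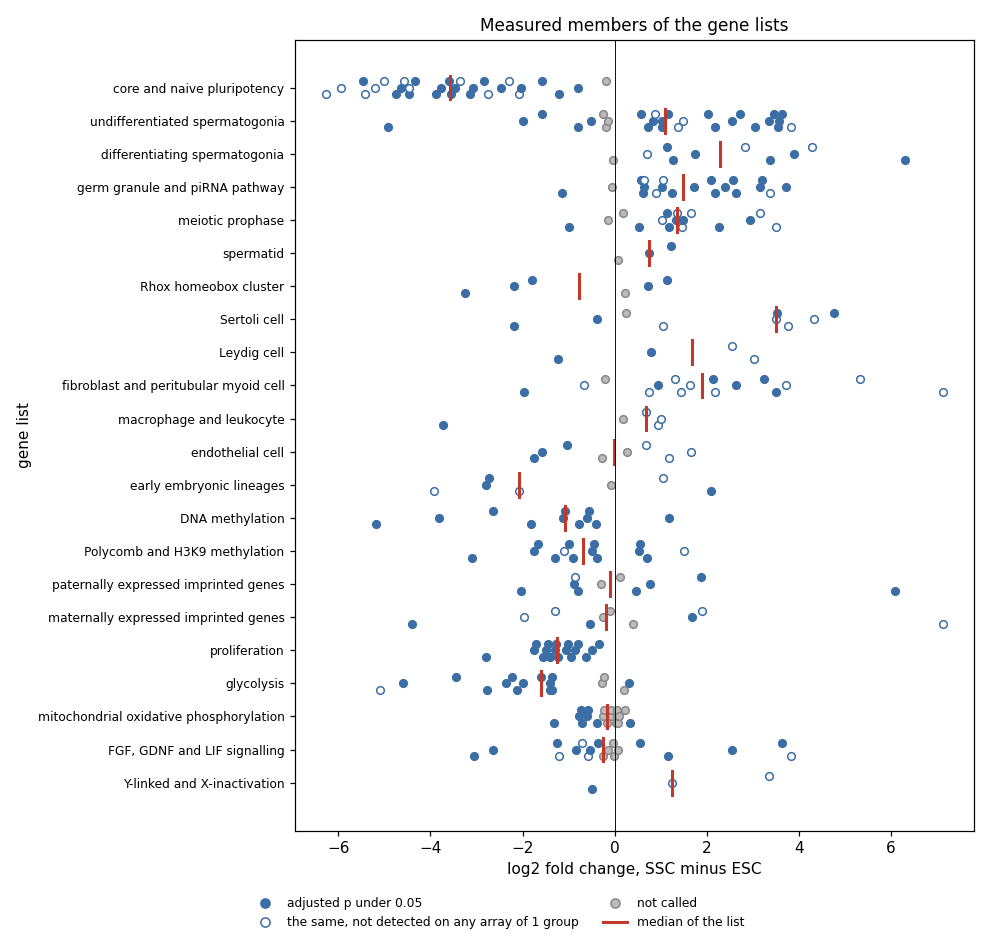
Fitted log2 fold change, SSC minus ESC (x axis), of each measured member of the 22 gene lists (y axis), with filled points for genes called at an adjusted p under 0.05, open points for genes not detected on any array of 1 group, grey points for genes not called, and a bar at each list's median. The pluripotency list lies to the left with a median of −3.58, and the germ granule list lies to the right with a median of 1.48.

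Genes that write, read or remove DNA methylation were lower in SSC. Of 11 measured members, 10 were lower and 1 was higher. Tet1, which oxidises methylcytosine, was lower by a difference of −5.18 ± 0.14, Dnmt3l, a cofactor of de novo methylation, by −3.81 ± 0.12, and the methyl-CpG-binding protein Mbd2 by −1.81 ± 0.13. Apobec1, detected on 2 of 3 SSC arrays, was at least 6.15-fold lower, while Mbd1 was higher (1.19 ± 0.16). The median was −1.08 (camera adjusted p = 0.00223, and adjusted p = 0.135 with an estimated correlation), or −0.565 without background correction and −0.580 from the authors' processed table. In the Polycomb and H3K9 methylation list, 10 of 14 were lower and 4 higher. Cbx7 (−3.10 ± 0.17), Ezh2, the Polycomb methyltransferase (−1.75 ± 0.13), Eed (−1.66 ± 0.12) and Phc1 (−1.30 ± 0.12, kept probes −2.45 to −0.91) were lower, while Bmi1 (at least 2.12-fold) and Cbx2 (0.70 ± 0.14) were higher, and the list was not called (adjusted p = 0.109).

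Imprinted genes went both ways. Of 10 measured paternally expressed genes, 4 were higher, 4 lower and 2 not called: Dlk1 and the growth factor gene Igf2 (1.87 ± 0.11) were higher, and Impact (−2.04 ± 0.13) and Mest (−0.88 ± 0.13, or −0.56 under scaling on array medians) were lower. The median (−0.089) and mean (0.44) differ in sign (adjusted p = 0.990). Of 10 maternally expressed genes, 3 were higher, 4 lower and 3 not called. Phlda2, a placental growth regulator, was lower (−4.39 ± 0.12), as was Slc22a18 (at least 3.13-fold), and Dcn and Ppp1r9a (1.69 ± 0.12) were higher. The other kept probe of Ppp1r9a was at −0.16, and the mean of its kept probes was 0.76. Here too the median (−0.18) and mean (0.26) differ in sign (adjusted p = 0.828).

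All 18 measured proliferation genes were lower in SSC, 12 of them at least 2-fold. Rrm2, a ribonucleotide reductase subunit, was lower by a difference of −2.79 ± 0.14, Kif11 by −1.75 ± 0.22, Aurka by −1.70 ± 0.12 and Cdk1, the mitotic kinase, by −1.55 ± 0.11. The kept probes of Rrm2 ranged from −2.79 to 0.12, with a mean of −1.82. The median was −1.25 (camera adjusted p = 2.65e-05, and adjusted p = 0.194 with an estimated correlation). Of 17 measured glycolysis genes, 13 were lower, all at least 2-fold, 1 was higher and 3 were not called. The glucose transporters Slc2a3 (at least 23.5-fold) and Slc2a1 (−3.44 ± 0.11) were lower, as were the phosphofructokinase Pfkp (−4.60 ± 0.12, other kept probe −2.62) and the lactate dehydrogenase Ldha (−2.77 ± 0.12). Pgk1, an X-linked enzyme, was higher (0.32 ± 0.11, adjusted p = 0.0229), and its call was lost without ESC replicate 2 (0.31), ESC replicate 3 (0.27) or SSC replicate 2 (0.31). It was also lost under scaling on array medians (0.13), and turned to −0.11 under scaling on probes detected on all arrays, chosen after seeing the data. The list's median was −1.61 (camera adjusted p = 2.65e-05, and adjusted p = 0.0819 with an estimated correlation).

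Of 19 measured genes of mitochondrial oxidative phosphorylation, 7 were lower, 1 was higher and 11 were not called, with a median of −0.17 (adjusted p = 0.228). Atp5a1 (−1.32 ± 0.13), Uqcrc1 (−0.78 ± 0.12), Ndufb5 (−0.73 ± 0.13) and Cox5a (−0.70 ± 0.12) were lower. Atp5a1 was at −0.77 with the mean of its kept probes, and under scaling on array medians Ndufb5 was at −0.44 and Cox5a at −1.11. Ndufa1 was higher (0.33 ± 0.12, adjusted p = 0.0209), a call lost without ESC replicate 1 (0.31), ESC replicate 2 (0.30) or SSC replicate 1 (0.28) and under scaling on probes detected on all arrays (0.048). The list's result depended on the scaling: its median was −0.441 under scaling on array medians (adjusted p = 0.00245) and −0.679 under scaling on probes detected on all arrays (adjusted p = 0.00142). The Polycomb list passed the threshold under scaling on array medians (adjusted p = 0.0372) and without a filter (adjusted p = 0.0484).

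In FGF, GDNF and LIF signalling, 9 of 19 measured genes were lower, 5 higher and 5 not called. Etv4 (−3.06 ± 0.12) and Bmp4 (−2.65 ± 0.14, other kept probe −1.38) were lower, and Id2 (3.64 ± 0.12), Ret and Gfra1 were higher. The median (−0.25) and mean (0.0089) differ in sign (adjusted p = 0.476). Of 3 measured genes of the Y chromosome, Usp9y (at least 7.90-fold) and Kdm5d (at least 1.61-fold) were higher and Eif2s3y was lower (−0.49 ± 0.13, or −0.31 under scaling on array medians), and the list was not called (adjusted p = 0.321). For each of the 22 lists, the counts adjusted over the list alone equalled those over all probes.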

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

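The comparison of array structure over alternatives and the scaling on probes detected on all arrays were chosen after seeing the data. The number of genes called stayed between 5579 and 7811 over all alternatives run, and between 7037 and 7316 with 1 sample left out. The count at 2-fold was 1409 without background correction and 1550 from the authors' table, whose values keep the background in both groups and so hold smaller ratios, and 2159 with detection on all 6 arrays, which tests fewer genes. Of the 3331 genes, 1405 were again called at 2-fold in the same direction without background correction. Scaling on array medians moved the median of all genes to 0.19, and 2920 of the 3331 kept their 2-fold call. Camera called 10 lists, 1 with an estimated correlation, where adjusted p-values were 0.188 for undifferentiated spermatogonia, differentiating spermatogonia and Sertoli cells, 0.120 for germ granules, 0.190 for meiosis, 0.194 for fibroblasts and proliferation, 0.135 for DNA methylation and 0.0819 for glycolysis. The estimated correlation was −0.056 for glycolysis, −0.066 for DNA methylation and −0.028 for Sertoli cells, under the preset 0.01. For the pluripotency list it was 0.0076, also under the preset, while camera's adjusted p rose from 4.28e-15 to 0.0234. A higher correlation between members therefore accounts neither for that rise nor for the calls lost for glycolysis, DNA methylation and Sertoli cells. In these lists the larger adjusted p-values at an estimated correlation do not show that members are correlated. Fry, which asks whether a list's members move on balance 1 way without comparing them with other genes, called 20 lists. Its direction was opposite for the macrophage (0.0043) and maternally expressed lists (0.186). With detection on all 6 arrays, Sertoli cells came to 0.872, fibroblasts to 0.128 and the Rhox cluster turned direction at 0.747, since that filter removes members undetected on any array and leaves 4, 6 and 3 of them. At an adjusted p under 0.01, Sertoli cells (0.0259) were not called. The paternally expressed list, not called in any camera setting, turned direction at 0.966 under cyclic loess, at 0.952 with the mean of kept probes and in 3 of 6 runs with a sample left out, over which its adjusted p was 0.904 to 0.998. Of 122 named genes, 118 kept call and direction in all settings run for them. With detection on all 6 arrays only 79 of the 122 were measured, so the rest were not tested in that setting. Kit was called with the mean of its kept probes (−0.32), and turned to 0.12 under scaling on array medians and ranged from −0.16 to 0.077 with a sample left out. Dhh, Ndufa1 and Pgk1 lost calls in several settings, and their adjusted p-values of 0.0184, 0.0209 and 0.0229 lie above 0.01, a threshold not planned for named genes. Pgk1 turned to −0.11 under scaling on probes detected on all arrays. The mean correlation between arrays of different groups was 0.790, and 0.829 without background correction, 0.827 from the authors' table, 0.899 without a filter, 0.823 with detection on all 6 arrays, 0.818 at a detection limit of 0.05 and 0.787 to 0.795 with a sample left out. The cause of the other changes was not tested. The replicate block gave 7348 genes, 3331 at 2-fold and 10 lists, and turned only the paternally expressed list (0.998). The numbers were not found to pair the samples: deviations from the group means correlated at −0.14, −0.068 and 0.030 for equal numbers, and of the 6 samples 1, SSC replicate 3, correlated best with its own number. Genes near the signal of undetected probes have only bounds.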

Other observations

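The tests of X-linked genes, of carried-over RNA and of the marker lists without background correction were chosen after the results were seen. X-linked genes were over-represented among those higher in SSC. Of 358 measured X-linked genes, 112 (31.3%) were at least 2-fold higher and 49 (13.7%) at least 2-fold lower, against 16.9% and 15.8% of 9649 autosomal genes. In a 1-sided permutation test, 0 of 10000 random sets of autosomal genes matched on mean level reached that share (p = 1e-04, the smallest they can give, with genes treated as independent). Their highest share was 24.3%. The share of X-linked genes exceeded the autosomal share under each scaling tried, from 14.2% against 7.34% without background correction to 37.7% against 21.3% under scaling on array medians. Examples were Tmem255a (at least 202-fold), Capn6 (at least 47.1-fold) and Mageb4 (at least 35.4-fold), and 40 of the 112 were not detected in ESC. Over genes detected on all 6 arrays the X-linked median was 0.093 and the autosomal −0.076. No cause of the X-linked excess was tested. The same data gave the idea and the test, and a contribution of other cells in the SSC samples remains open.

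Most measured genes of the Sertoli cell list and of the fibroblast and peritubular myoid list were higher in the SSC samples. The samples may hold RNA of such cells, or the germ cells may express these genes themselves. A second Sertoli list of 14 genes, 0 of them on another list, was written before their values were seen. Of its 9 measured members 8 were higher, 5 of these undetected in ESC, from Mro (at least 11.5-fold) to Trf (0.32), and Cst12 was not called (0.15). Sertoli cell RNA was taken beforehand to need most measured members higher and a median of at least 1. The fitted values met both, with a median of 1.35. That median was 0.903 with bounds and 0.411 without background correction, settings that the prediction did not name. Since it depends on them, the list does not settle the question. A list of 18 genes abundant in cultured fibroblasts, written in the same way and held to the same limit, had 11 of 14 measured members higher, 1 lower (Timp1, −2.29) and 2 not called, with a median of 1.15 (1.03 with bounds, 0.551 without background correction). Sertoli cells, feeder cells and stromal cells of the testis all stay open as sources, expression by the spermatogonia was not tested, and no sort is named that would remove other cells.

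Germ cell genes were detected in ESC and pluripotency genes in SSC, and RNA carried over between samples is a possible explanation. Carry-over would leave every abundant gene at the carried share, and the median of the 10 lowest ESC to SSC ratios among 1082 abundant SSC genes limits it to 0.308% of the SSC signal. The 24 higher spermatogonial and germ granule genes detected on all 3 ESC arrays stood at 5.35% to 66.5% of their SSC signal, with Ddx4 at 28.7%. In the other direction the limit was 0.892%, and the 15 pluripotency genes lower in SSC and detected on all SSC arrays stood at 3.43% to 56.1% of their ESC signal, with Pou5f1 at 42.8%. Both limits argue against carry-over as the source, while expression in the cells themselves and probes that bind other transcripts stay open, and neither was tested.

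With 3 samples against 3 there are 10 splits, too few for a share under 0.05. Only 1 of them, the real one, gave as many called genes (7460, and 0 in limma for the highest of the others, which had 45 genes at an unadjusted p under 0.05 against 7622), and 1 gave as many at 2-fold (3331, the highest other 0). Each other split has both cell types on each side, so their difference widens the spread there and leaves few gene calls. These gene counts therefore do not bear on whether the grouping arose by chance. For gene lists 1 split reached the real count of 10, and the highest other had 9. Each other split is uneven, with more ESC samples on 1 side and more SSC samples on the other. It so keeps part of the difference between the cell types, and the same lists can be called there. The list counts therefore bear neither on whether the grouping arose by chance nor on how often camera calls lists that are not shifted. Strain and cell type coincide in these samples, so no difference reported here can be told apart from a difference between R1/E and C57BL/6 cells by the labels.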
